A study of Eucalyptus grandis
Pisolithus microcarpus and Eucalyptus grandis with 23 samples.

How the data were processed

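RNA was sequenced from 23 root libraries of 6 groups, which the labels define by fungal strain and by CO2 at 400 or 650 ppm. Per the labels' protocols, seedlings were grown in Petri dishes with or without a square of mycelium and RNA was sequenced as read pairs. The deposited tables hold, for each gene, its length, the count of unique gene reads, the count of total gene reads and an RPKM. The deposited RPKM equals total reads per kilobase of length, scaled to the gene reads of the library, for all 36376 genes of each library, within 1% plus rounding, and was not used further. Per the file headers of 2 control libraries, pairs were trimmed before an RNA-Seq step; the aligner, the genome build and the strand setting are not given in the sources used here. Reads that matched 1 gene only made up 95.7% to 96.5% of a library's gene reads, and 5851 of the tested genes had under 90% of such reads, so their counts are uncertain.

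Total gene reads were tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), 2-sided, with TMM factors, filterByExpr by group and Benjamini-Hochberg adjustment at 0.05. All 23 libraries entered 1 fit with 1 mean per group and 17 residual degrees of freedom, and 12 contrasts were taken from it. CPM values are scaled by TMM factors. Standard errors are those implied by the test statistic. Where a group had no reads of a gene, the fold is a bound against 3 counts over that group. Gene totals per library ran from 4497662 to 30210474 reads, so 3 counts correspond to 0.0993 to 0.667 CPM in a single library, and lower levels there rest on fewer than 3 reads. DESeq2 1.42.0 served as an alternative, and figures were drawn with matplotlib 3.10.9.

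Groups, tests, contrasts, gene lists and the rule for named genes were fixed before the data were examined. The rule takes genes past the threshold whose CPM do not overlap between the groups, with at least 1 CPM in the higher group, and names the 2 with the largest rise and the 2 with the largest fall; for the 3 interactions the overlap condition is dropped. Without descriptions of the genes the rule allows no more names. The 44 gene lists, among them markers of other root tissues, were text patterns on gene descriptions and were not applied, because 0 of the 36376 IDs matched a row of the reference table (assembly ASM1654582v1). Alternatives fixed in advance were other scaling factors, other filters, DESeq2, fits of only the groups compared, blocks for replicate number or library run, a 2-fold minimum, controls of the same library run, and each library left out. Library runs are numbers 1 to 12 and 13 to 24 in the deposited names. Controls fall in both runs, SI-9 roots in the first and SI-12 roots in the second.

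After the data were seen, libraries of a group that differed by a coefficient of variation under 0.2 were also summed into 10 sets, each taken as 1 replicate with 4 residual degrees of freedom. The main test kept them separate, as fixed in advance from the labels, which call them biological replicates. Their spread exceeds counting noise, with a mean chi-square per gene of 3 to 62.7, as repeat preparations of 1 RNA pool could also do. The main test was tested on simulated data with 200 changed genes per comparison among 26756, where libraries were drawn independently and without near-identical sets. For elevated CO2 in control roots it recovered 0.58 of genes changed 2-fold and 0.78 of those changed 4-fold. The shares were 0.49 and 0.76 for SI-9 against control roots at 400 ppm and 0.36 and 0.71 for elevated CO2 in SI-12 roots, with 3 to 6 false calls. A second simulation drew unchanged groups 10 times, with sets that differ by the spread fitted to the 10 real sets. SI-9 library 2 at 400 ppm was among these. Libraries of a set differed by a small spread, chosen in advance and the same in every set. There the main test gave medians of 1784 to 5902 false calls per comparison.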

Results

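Gene expression was measured by RNA sequencing in roots of Eucalyptus grandis seedlings grown in vitro, alone or in contact with a strain of the ectomycorrhizal fungus Pisolithus microcarpus, which forms a sheath around fine roots of eucalypts. The strains were SI-9 and SI-12, and each combination was kept at 400 or 650 ppm CO2. Control roots had 6 libraries at 400 ppm and 5 at 650 ppm, and each of the 4 mycorrhizal groups had 3, giving 23 libraries. Reads assigned to genes ranged from 4497662 in SI-9 library 1 at 400 ppm to 30210474 in control library 1 at 400 ppm. The tables list 36376 genes, of which 27386 had enough reads to be tested. Genes are given by the IDs of the files, which do not pair them with names.

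Libraries of the same group fell into near-identical sets. At 400 ppm, control libraries 1 to 3 differed from each other, and libraries 4 to 6 from each other, by a coefficient of variation of 0.0632 to 0.0957 beyond counting noise, whereas libraries 1 to 3 differed from libraries 4 to 6 by 0.42 to 0.438. At 650 ppm, control libraries 1 and 2 differed from libraries 3 to 5 by 0.237 to 0.242, against 0.0582 to 0.0764 inside those sets. SI-9 library 3 at 650 ppm differed from libraries 1 and 2 by 0.484 to 0.496, while libraries 1 and 2 differed by 0.0614. The 3 SI-12 libraries lay within 0.151 of each other at 400 ppm and within 0.0928 at 650 ppm. Pairs from different groups differed by 0.29 to 0.6, a range that takes in the difference between the sets of control libraries at 400 ppm. The labels describe the libraries of a group as biological replicates, and the p-values below measure the spread between libraries, which inside these sets may be technical. Counts of called genes are therefore printed with the count obtained when each of the 10 sets was taken as 1 replicate. The SI-12 libraries form 1 set at each CO2 level, as does SI-9 at 400 ppm without library 2, so in those tests such a lone set is assumed to vary like the sets of the other groups. Of the 48 calls of named genes below, 46 were lost in that edgeR test and 7 with DESeq2 on the same sets, which kept 39. The fitted changes kept their direction, as for Eucgr.C04162.1 under elevated CO2 in control roots, with log2 fold changes of 11.18 with libraries and 11.28 with sets. The adjusted p-values printed with named genes are those with 23 libraries unless sets are named. The calls of Eucgr.H02209.1 and Eucgr.I00503.1 in the interaction of SI-9 with CO2 were kept, but both were lost when SI-9 library 2 at 400 ppm was left out of the sets. In that test with 9 sets the calls of Eucgr.E00380.1 in SI-12 roots at 400 ppm and of Eucgr.E03505.1 in SI-9 roots at 650 ppm passed.

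**Figure D1:**
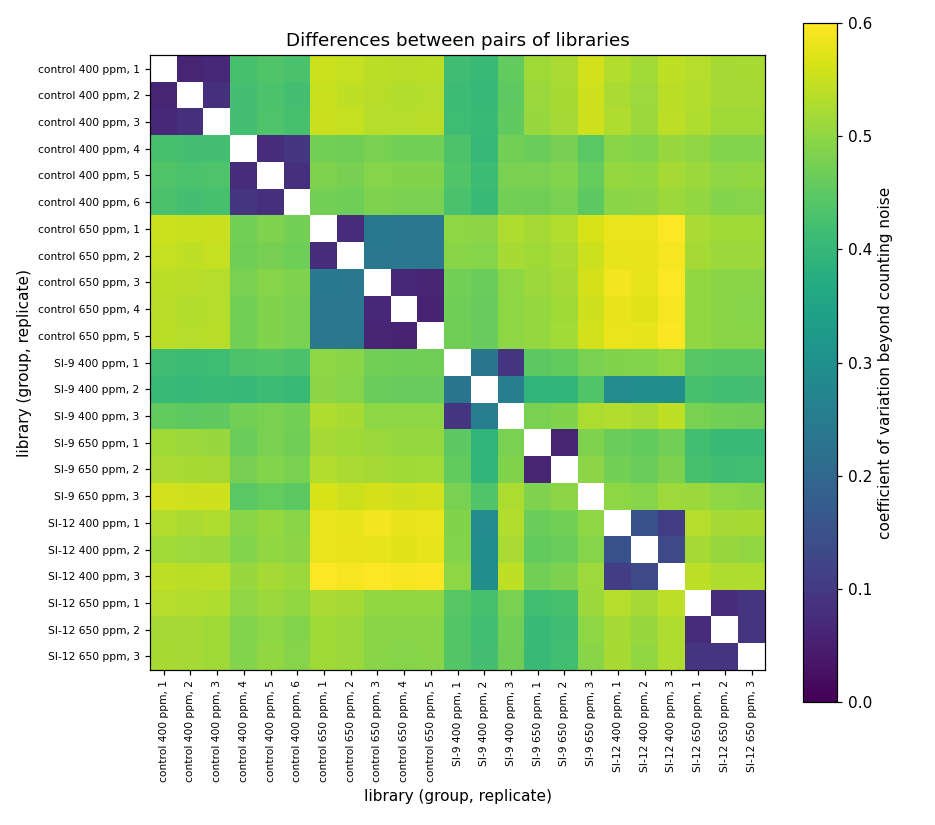
Each square is a pair of libraries, coloured by the coefficient of variation between their read counts beyond counting noise, with libraries ordered by group and replicate on both axes. Dark blocks are the near-identical sets, in which pairs differed by 0.0582 to 0.151, and SI-9 library 2 at 400 ppm lies closer to the SI-12 libraries at 400 ppm than its group does.

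SI-9 library 2 at 400 ppm had reads of genes that SI-9 libraries 1 and 3 lacked and SI-12 roots at 400 ppm expressed. Eucgr.G02153.1 had 18.8 CPM in this library and 0 in libraries 1 and 3, and averaged 42.1 ± 5.63 CPM (SD, n = 3) in SI-12 roots at 400 ppm. Eucgr.C04162.1 had 135.5 CPM there, against 253.8 and 246.7 CPM in libraries 1 and 3 and 0.281 ± 0.0918 CPM (SD, n = 3) in the SI-12 roots. The 21 genes found in SI-12 roots and not in SI-9 libraries 1 and 3 stood at a median of 0.404 of their SI-12 level, and the 5 genes found the other way round at 0.548 of their SI-9 level. Among 266 further genes, at 1 to 10 CPM in SI-12 roots and under 0.1 CPM in SI-9 libraries 1 and 3, the median was 0.445, with 8 genes at 0 and 23 at 0.8 or more. Counts for comparisons that use this group are also given without this library.

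**Figure D2:**
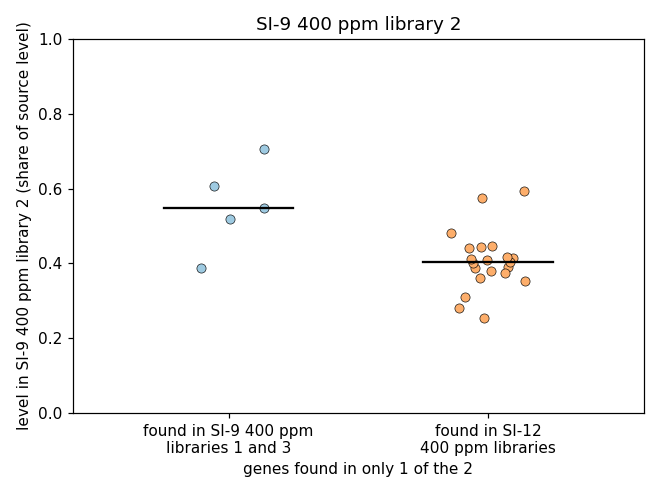
Points are genes found in only 1 of the sources at 400 ppm (SI-9 libraries 1 and 3, or the SI-12 libraries), and the vertical axis is their level in SI-9 library 2 as a share of the level in that source, with the median as a line. The medians are 0.548 and 0.404, and the genes lie between 0.254 and 0.705.

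Eucgr.B01584.1 was the most abundant transcript of the SI-12 roots at 650 ppm. It took 4.07%, 7.53% and 16.2% of the gene reads in these 3 libraries, with exact 95% binomial intervals of 4.06% to 4.08%, 7.52% to 7.55% and 16.18% to 16.22%. Its share lay between 1.96% and 2.95% in the SI-9 libraries at 400 ppm, between 0.233% and 1.59% in those at 650 ppm, between 0.27% and 0.42% in the SI-12 libraries at 400 ppm, and between 0.157% and 0.578% in the control libraries. Such intervals cover counting error only, since reads made by amplification are not independent molecules.

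**Figure D3:**
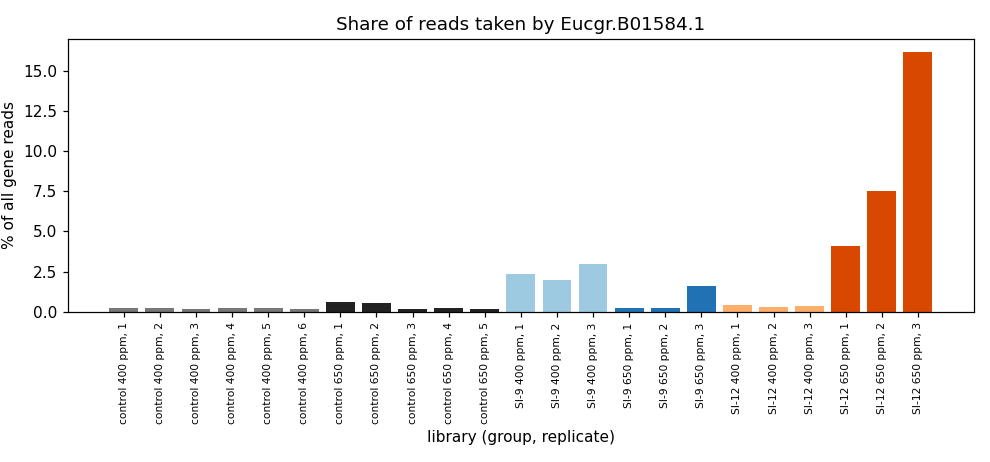
Bars give the reads of Eucgr.B01584.1 as a percentage of all gene reads in each of the 23 libraries, coloured by group. The bars of the SI-12 libraries at 650 ppm stand at 4.07%, 7.53% and 16.2%.

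The first comparison asked how elevated CO2 alone changes the root transcriptome. Among genes that rose in control roots at 650 ppm, Eucgr.C04162.1 went from 0.0807 ± 0.0956 CPM (SD, n = 6) to 209 ± 38.9 CPM (SD, n = 5), a log2 fold change of 11.18 with an SE of 1.05 (adjusted p = 3.85e-08). Eucgr.G02153.1 had no reads in the 6 libraries at 400 ppm and 48.3 ± 5.02 CPM (SD, n = 5) at 650 ppm, at least 2130-fold higher by a floor of 3 counts over the group (adjusted p = 6.87e-05), although 64.9% of its reads matched 1 gene only. Eucgr.B02918.1 fell from 38.7 ± 9.78 to 0.0133 ± 0.0298 CPM (adjusted p = 8.5e-08), and Eucgr.C03634.1 from 11.7 ± 4.22 CPM to no reads, at least 402-fold lower (adjusted p = 6.94e-07). Each gene named here and in the other comparisons of a pair of groups had no overlap between the libraries of these groups. In all, 5477 genes rose and 6169 fell. Controls of each library run gave 11468 and 10846 called genes on their own. Of these, 5248 were called in both runs in the same direction and 887 in opposite directions, where independent lists would share 2217 of each kind. With sets as replicates 224 genes rose and 215 fell (439 in all), against 97 in all with SI-9 library 2 at 400 ppm left out of the sets and 3139 by DESeq2 on the 10 sets. Unchanged groups simulated with the same sets gave a median of 5598.5 calls, and control libraries of the same CO2 level differed between runs in 8031 genes at 400 ppm and 2559 at 650 ppm.

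**Figure D4:**
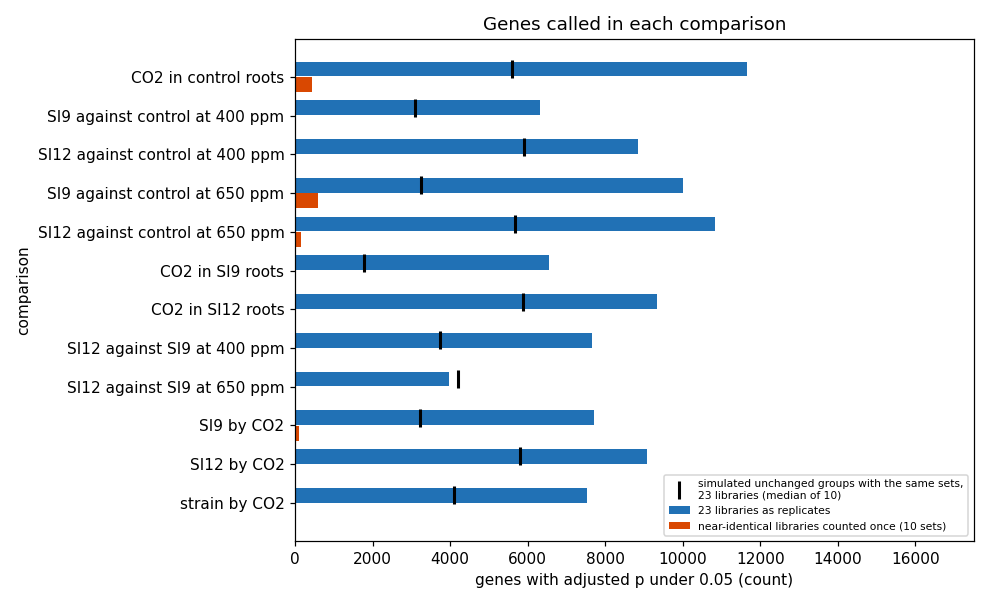
Blue bars give the genes with adjusted p under 0.05 in each comparison with 23 libraries as replicates, orange bars the number with near-identical libraries counted once, and black marks the median of 10 simulations of unchanged groups with the same sets. The blue bars reach from 3981 to 11646 genes and the orange bars from 0 to 584.

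The next question was what each fungal strain changes in the root at 400 ppm. In SI-9 roots, Eucgr.C04162.1 was higher than in control roots, at 212 ± 66.3 CPM (SD, n = 3), with a log2 fold change of 11.20 and an SE of 1.08 (adjusted p = 3.51e-07). Eucgr.B03129.1 had 6.63 ± 3.45 CPM (SD, n = 3) and no reads in the controls, at least 292-fold higher (adjusted p = 1.5e-06). Eucgr.C02944.1 stood at 30.1 ± 7.32 CPM (SD, n = 6) in controls and had no reads in SI-9 roots, at least 291-fold lower (adjusted p = 0.00494). Eucgr.C03346.1 was at least 61.1-fold lower (adjusted p = 0.00482), but its control level of 6.32 ± 6.39 CPM (SD, n = 6) came from libraries 1 to 3, and its call was lost when the fit held only these groups. Altogether 3098 genes rose and 3228 fell, and 6118 were called without SI-9 library 2. The count was 4100 without SI-9 library 1 and 3778 without library 3. With sets as replicates edgeR called 0 genes, with 3531 at an unadjusted p under 0.05, and DESeq2 called 1181. Unchanged groups simulated with the same sets gave a median of 3086 calls.

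SI-12 roots at 400 ppm were set against the same 6 control libraries. Eucgr.G02153.1 was at least 1850-fold higher in SI-12 roots (adjusted p = 0.000196), and Eucgr.L00508.1, with 59.8% of its reads matching 1 gene only, had 36.7 ± 7.45 CPM (SD, n = 3) and no reads in the controls, at least 1620-fold higher (adjusted p = 9.38e-07). Eucgr.E00380.1 had 29 ± 3.54 CPM (SD, n = 6) in controls and no reads in the 3 SI-12 libraries, at least 346-fold lower (adjusted p = 6.37e-12). The 5 other groups kept this gene at means of 11.5 to 29 CPM. Eucgr.C02944.1 had no reads in SI-12 roots either, at least 359-fold lower (adjusted p = 0.00218). The test called 3969 genes higher and 4867 lower. Taking sets as replicates, edgeR called 0, with 3597 at an unadjusted p under 0.05, and DESeq2 called 1452 (4 by edgeR without SI-9 library 2), while unchanged groups simulated with the same sets gave a median of 5902.

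At 650 ppm, SI-9 roots had 15.1 ± 13 CPM (SD, n = 3) of Eucgr.C03474.1, which had no reads in the 5 controls, at least 521-fold higher (adjusted p = 2.4e-05). Libraries 1 and 2 held 22.2 and 23.1 CPM of it and library 3 held 0.122, and 58.5% of its reads matched 1 gene only. Eucgr.L02796.1 was at least 319-fold higher (adjusted p = 0.00365), with 0.0406 CPM in library 3, under the level of 3 counts there (0.123 CPM). Eucgr.A02524.1 fell from 20.9 ± 1.8 CPM (SD, n = 5) to no reads, at least 473-fold lower (adjusted p = 7.51e-05), and Eucgr.E03505.1 from 17.3 ± 1.71 CPM (SD, n = 5) to no reads, at least 392-fold lower (adjusted p = 2.41e-06). The test called 5284 genes higher and 4723 lower. On the level of sets 271 rose and 313 fell (584 in all), against 161 without SI-9 library 2 at 400 ppm and 3617 by DESeq2, and unchanged groups simulated with the same sets gave a median of 3246 calls.

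SI-12 roots at 650 ppm shared part of this change. Eucgr.C03474.1 reached 26.5 ± 5.44 CPM (SD, n = 3), at least 914-fold above the controls (adjusted p = 8.51e-06), and Eucgr.L00712.1 reached 18.7 ± 2.27 CPM (SD, n = 3) against no reads, at least 643-fold higher (adjusted p = 1.99e-05). Eucgr.A02524.1 had no reads, at least 312-fold lower (adjusted p = 0.00011). Eucgr.G02055.1 was at least 490-fold lower (adjusted p = 0.000173), from a control level of 32.8 ± 24.8 CPM (SD, n = 5), with 79.8% of its reads matching 1 gene only. Control libraries 1 and 2 held 59.17 and 60.74 CPM of it, and libraries 3 to 5, of the library run of SI-12, 14.43 to 15.02 CPM. In total 5447 genes rose and 5395 fell. On the level of sets 83 rose and 67 fell (150 in all), against 13 without SI-9 library 2 at 400 ppm and 2479 by DESeq2, and unchanged groups simulated with the same sets gave a median of 5681 calls.

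**Figure D5:**
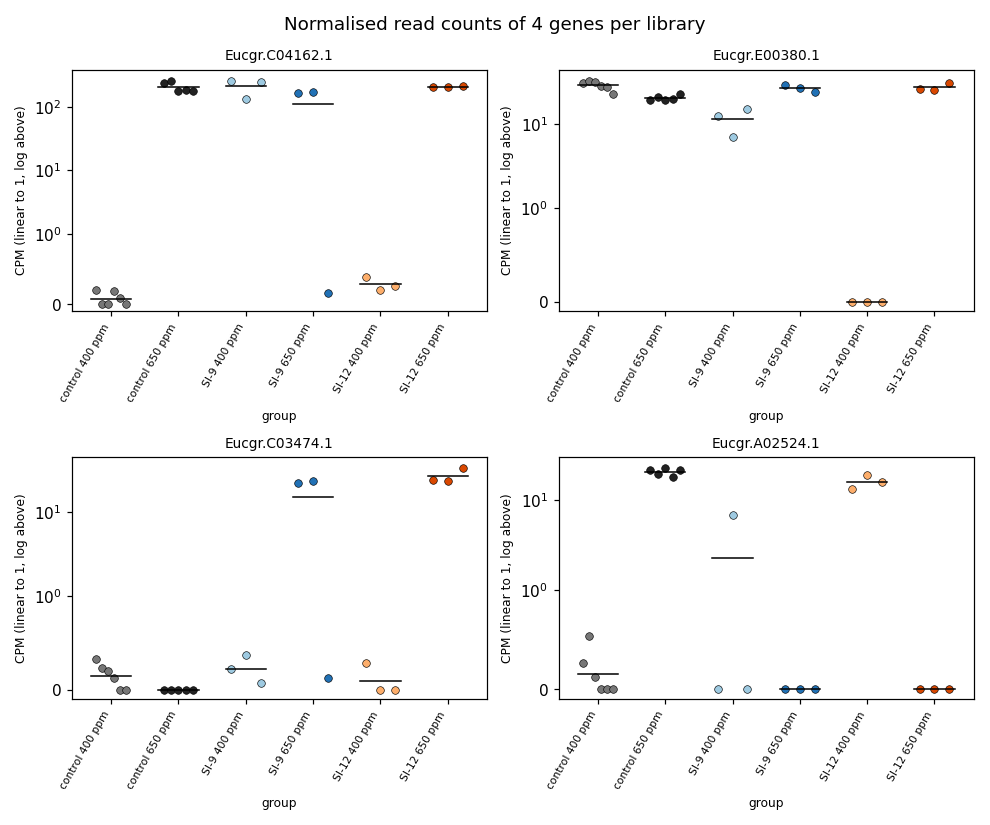
Normalised read counts (CPM, linear up to 1 and logarithmic above) of 4 genes in each library, by group, with the group mean as a line. Eucgr.E00380.1 has no reads in the 3 SI-12 libraries at 400 ppm, and SI-9 library 3 at 650 ppm lies apart from its group for Eucgr.C04162.1 and Eucgr.C03474.1.

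Responses to the strains were then compared. At 650 ppm, 6206 genes were called in the same direction in SI-9 and SI-12 roots (3162 higher, 3044 lower) and 194 in opposite directions. Independent lists would share 1051 higher and 930 lower genes and hold 1980 in opposite directions. Across genes, which are not independent replicates, the changes in both strains correlated with r = 0.629, and with r = 0.526 when each strain had the controls of its own library run. Unchanged groups of independent libraries, simulated against shared controls without the differences between sets, gave r = 0.363, a value to set against 0.629 only. With each strain set against the controls of its own library run, 5683 genes moved the same way and 568 the opposite way. At 400 ppm, 2486 genes moved the same way (1240 higher, 1246 lower) and 509 the opposite way, where independent lists would share 449 higher and 574 lower genes and hold 1018 in opposite directions. The correlation there was 0.544, against 0.278 in that simulation with shared controls. It was 0.274 with controls of the own library run, where the strains share no control libraries and no value was simulated. There the split of the controls gave 2545 the same way and 1355 the opposite way, with 1476 and 1484 for independent lists. Leaving out SI-9 library 2 lowered the number at 400 ppm to 1737. Unchanged groups simulated with near-identical sets shared a median of 1102.5 genes at 400 ppm and 1175.5 at 650 ppm. For sets as replicates, 0 genes were shared at 400 ppm by edgeR and 464 by DESeq2, and at 650 ppm 112 by edgeR (12 without SI-9 library 2 at 400 ppm) and 1481 by DESeq2.

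Elevated CO2 was also compared within mycorrhizal roots. In SI-9 roots, Eucgr.E02300.1 had 3.76 ± 0.298 CPM (SD, n = 3) at 650 ppm and no reads at 400 ppm, at least 36.4-fold higher (adjusted p = 0.000405). Eucgr.H02015.1 was at least 25.4-fold higher, with an adjusted p of 0.0479 that most single-library omissions moved past the threshold. In library 3 at 650 ppm it stood at 0.0406 CPM, under the level of 3 counts there (0.123 CPM). Eucgr.K02158.1 fell from 12.6 ± 5.17 CPM (SD, n = 3) to no reads, at least 286-fold lower (adjusted p = 5.3e-07). Eucgr.C04248.1 fell from 15 ± 5.24 CPM (SD, n = 3) to no reads, at least 339-fold lower (adjusted p = 4.14e-09), with 55.4% of its reads matching 1 gene only. Of the genes tested, 3279 rose and 3278 fell, and 3266 in all were called when the fit held only these groups. Without SI-9 library 2 at 400 ppm 6966 were called. Taking sets as replicates, edgeR called 0, with 4718 at an unadjusted p under 0.05, and DESeq2 called 2061, while unchanged groups simulated with the same sets gave a median of 1784.

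In SI-12 roots, Eucgr.L00601.1 had 44.2 ± 1.26 CPM (SD, n = 3) at 650 ppm and no reads at 400 ppm, at least 527-fold higher (adjusted p = 7.02e-05), and Eucgr.C02944.1 was at least 357-fold higher (adjusted p = 0.00268). Eucgr.I00076.1 fell from 50.5 ± 3.37 CPM (SD, n = 3) to no reads, at least 755-fold lower (adjusted p = 2.4e-07), with 66.2% of its reads matching 1 gene only. Eucgr.L03047.1 was at least 272-fold lower (adjusted p = 0.025), with 81.3% of its reads matching 1 gene only, a call lost when any of the SI-12 libraries at 650 ppm was left out. At 650 ppm 4817 genes were called higher and 4529 lower than at 400 ppm. Each CO2 level holds a single set of SI-12 libraries, so CO2 cannot be told apart from another difference between these sets. On the level of sets edgeR called 0, with 3710 at an unadjusted p under 0.05, and DESeq2 called 1392 (3 by edgeR without SI-9 library 2 at 400 ppm), while unchanged groups simulated with the same sets gave a median of 5887.

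The strains were compared directly at each CO2 level. All SI-9 libraries are of the first library run and all SI-12 libraries of the second, so strain and run coincide in these comparisons. Control libraries differed between runs in 8031 genes at 400 ppm and 2559 at 650 ppm. With library run as a block, 6612 genes were called between strains at 400 ppm and 5195 at 650 ppm. That block assumes a run effect shared by both CO2 levels, whereas the run differences of 400 and 650 ppm controls correlated with r = -0.0623. These counts therefore do not separate strain from run. At 400 ppm, Eucgr.C01632.1 was at least 15.9-fold higher in SI-12 than in SI-9 roots (adjusted p = 0.00585), with 44.9% of its reads matching 1 gene only, and Eucgr.L00903.1 at least 11.7-fold higher (adjusted p = 0.016), with 86.4% of such reads and a call lost without SI-9 library 3. They averaged 1.64 and 1.21 CPM in SI-12 roots and had no reads in SI-9 library 2. Eucgr.G02153.1, with 18.79 CPM in that library and 0 in libraries 1 and 3, was not named by the rule here. Eucgr.L00601.1 had 23.4 ± 9.39 CPM (SD, n = 3) in SI-9 roots and no reads in SI-12 roots, at least 280-fold lower (adjusted p = 0.000385). Eucgr.L03521.1 was at least 175-fold lower (adjusted p = 0.000273), with 88.6% of its reads matching 1 gene only. In this comparison 3454 genes were higher and 4214 lower in SI-12 roots. Without SI-9 library 2, which held reads of genes found in SI-12 roots, 8950 were called, 4391 higher and 4559 lower. Leaving out SI-9 library 1 or 3 gave 5026 and 4484. For sets as replicates edgeR called 0, with 3101 at an unadjusted p under 0.05 (2 called without SI-9 library 2). DESeq2 on the sets called 806, 47 higher and 759 lower. Unchanged groups simulated with the same sets gave a median of 3731.5.

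At 650 ppm, Eucgr.L01984.1 had 14.1 ± 0.427 CPM (SD, n = 3) in SI-12 roots and no reads in SI-9 roots, at least 320-fold higher (adjusted p = 4.82e-05), with 67.4% of its reads matching 1 gene only, and Eucgr.K02209.1 was at least 163-fold higher (adjusted p = 0.00987). Eucgr.E02674.1 was at least 238-fold lower in SI-12 roots (adjusted p = 4.64e-05), with 78.8% of its reads matching 1 gene only. Eucgr.B01194.1 had 9.69 ± 5.58 CPM (SD, n = 3) in SI-9 roots and no reads in SI-12 roots, at least 145-fold lower (adjusted p = 0.00644), a call lost with library run as a block. This comparison gave the fewest calls of the 12, with 1786 genes higher and 2195 lower. Their sum of 3981 lies under the 3995 to 4297 calls that unchanged groups simulated with the same sets gave. Leaving out SI-12 library 1, 2 or 3 gave 2527, 2576 and 2614. Taking sets as replicates, edgeR called 0, with 2241 at an unadjusted p under 0.05, and DESeq2 called 568.

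Whether the response to a fungus differed between CO2 levels was tested as an interaction. The response to SI-9 was lower at 650 than at 400 ppm for Eucgr.H02209.1 and Eucgr.I00503.1 (adjusted p = 1.06e-07 and 1.41e-09), and both passed with 10 sets as replicates (adjusted p = 0.0196 and 0.0097) but not with SI-9 library 2 at 400 ppm left out of the sets. Eucgr.I00503.1 had 12.3 ± 6.45 CPM (SD, n = 3) in SI-9 roots at 400 ppm and 14.4 ± 3.34 CPM (SD, n = 5) in control roots at 650 ppm, with means of 0.0453 CPM or less in the other 4 groups. Eucgr.H02209.1 had 2.83 ± 1.08 CPM (SD, n = 3) and 5.93 ± 1.38 CPM (SD, n = 5) in the same groups. Eucgr.J01742.1 and Eucgr.H02815.1 had a higher response at 650 ppm (adjusted p = 0.0103 and 0.0019), with means of 8.27 ± 7.17 and 3.67 ± 6.35 CPM (SD, n = 3) in SI-9 roots at 650 ppm and no reads in those at 400 ppm. At 400 ppm the control level of Eucgr.J01742.1 came from libraries 4 to 6, of the other library run than SI-9, and libraries 1 to 3 had no reads of it. Within the SI-9 group at 650 ppm, library 3 had no reads of Eucgr.J01742.1 and was the only library with reads of Eucgr.H02815.1, whose call was lost without it. The interaction called 4078 genes with a higher and 3645 with a lower response at 650 ppm, and 7900 in all without SI-9 library 2 at 400 ppm. On the level of sets edgeR called 47 and 54 (101 in all) and DESeq2 1875, but without SI-9 library 2 at 400 ppm edgeR called 0, with 4084 at an unadjusted p under 0.05, and unchanged groups simulated with the same sets gave a median of 3224.5.

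For SI-12, Eucgr.A02524.1 and Eucgr.J00375.1 had a lower response at 650 ppm (adjusted p = 5.05e-06 and 0.000126). Eucgr.A02524.1 stood at 16.1 ± 2.91 CPM (SD, n = 3) in SI-12 roots at 400 ppm and had no reads in them at 650 ppm, while control roots went from 0.152 ± 0.212 CPM (SD, n = 6) to 20.9 ± 1.8 CPM (SD, n = 5). Eucgr.E02341.1 and Eucgr.C01795.1 had a higher response at 650 ppm (adjusted p = 0.00582 and 0.000145). Eucgr.E02341.1 had 5.31 ± 0.459 CPM (SD, n = 3) in SI-12 roots at 650 ppm and no reads in those at 400 ppm. It lost its call with replicate number as a block. Its control level at 400 ppm came from libraries 4 to 6 alone, which that block fit left out. The interaction called 4959 genes higher and 4121 lower, with 13 and 8 (21 in all) when sets were the replicates, 3 without SI-9 library 2 at 400 ppm and 1285 by DESeq2 on the 10 sets, and unchanged groups simulated with the same sets gave a median of 5796. The CO2 response differed between strains for 3826 genes higher and 3694 lower in SI-12 roots, and for 8583 in all without SI-9 library 2 at 400 ppm. Among them, Eucgr.C04248.1 and Eucgr.F04170.1 had a higher response (adjusted p = 2.1e-10 and 0.000398), and Eucgr.E02674.1 and Eucgr.L03047.1 a lower one (adjusted p = 9.4e-06 and 0.0282). Eucgr.F04170.1 went from 9.94 ± 2.16 to 0.0401 ± 0.0399 CPM in SI-9 roots and from no reads to 3.09 ± 0.906 CPM in SI-12 roots (SD, n = 3). The call of Eucgr.L03047.1 was lost without SI-9 library 1 or 3 at 400 ppm or any SI-12 library at 650 ppm. For sets as replicates edgeR called 0 for this difference, with 3644 at an unadjusted p under 0.05, and DESeq2 called 1134, while unchanged groups simulated with the same sets gave a median of 4093.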

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

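The outlier and interaction checks were fixed in advance, and the tests on plant material, library runs, SI-9 library 2 at 400 ppm and reads of Eucgr.B01584.1 were chosen after the results were seen, except those on thinned depth and on genes that respond to SI-9; the restriction of the latter to genes of at least 1 CPM came after its first value. Among 74 pairs of a named gene and a control group, 5 had a library far from the others. For independent, normally distributed values the bound gives about 1 in 20. Pairs without reads in the whole control group could not be flagged, and libraries in near-identical sets may not be independent. The number flagged is therefore not weighed against that rate. Control library 2 at 650 ppm held 57.2 CPM of Eucgr.G02153.1 (45.4 to 47.7 in the others) and 20.2 CPM of Eucgr.I00503.1 (12.3 to 13.8). Control library 3 at 650 ppm held 0.6 CPM of Eucgr.C01632.1 (0 to 0.166 in the others) and 0.0667 CPM of Eucgr.B02918.1, and control library 3 at 400 ppm held 0.0794 CPM of Eucgr.I00503.1. The last 2 values are 2 reads each, in groups otherwise at 0.

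Responses differed between CO2 levels in 7723 genes for SI-9 and 9080 genes for SI-12, and the CO2 response differed between strains in 7520 genes. With only the groups compared in the fit, and CO2 labels exchanged within each fungal status, 1 of 100 splits (the real one) gave as many calls in each case. The real splits called 6706, 9742 and 7192 genes, and the highest of the others 2675, 7239 and 5213. The 100 splits were taken from 9240 possible ones for SI-9 and for SI-12 and 200 for strain. Exchanging CO2 labels also removes a CO2 response common to both fungal statuses, so these splits do not test the interaction alone. Such splits treat near-identical libraries as independent too, so they do not separate treatment from the differences between sets.

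The same count was made for the other comparisons. Elevated CO2 in control roots gave 10992 genes and the highest of 99 other splits 7224 (1 of 100 as large). The 100 splits were taken from 462 possible ones. SI-12 roots against controls gave 7630 against 4562 at 400 ppm (1 of 84) and 12996 against 843 at 650 ppm (1 of 56). SI-9 roots at 650 ppm gave 9057 against 173 (1 of 56). In these comparisons the real split called more genes than any other split counted. These splits also treat near-identical libraries as independent, so a chance difference between sets is not excluded. The split behind 4562 sets control libraries 1 to 3 against all others and so follows a library run too. For SI-9 roots at 400 ppm 2 of 84 splits were as large: the real one gave 4570, and the split that sets control libraries 4 to 6, a library run, against all others gave 4657. Against controls of its own run this comparison gave 8001 genes. The 4 comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. Their real splits gave 3266 (CO2 in SI-9 roots), 12191 (CO2 in SI-12 roots), 7315 (strains at 400 ppm) and 3320 (strains at 650 ppm), with 0 in the highest of the others.

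Libraries of a group formed near-identical sets that differ from each other. A batch shared by both CO2 levels that follows the library numbers is argued against, since the differences between runs in 400 and 650 ppm controls had a correlation across genes of -0.0623, and genes are not independent replicates. Unequal depth is argued against too: with all libraries thinned to 4497662 reads, control libraries of different runs at 400 ppm still differed by at least 0.304, close to the bound of 0.3 set for that test, and the 6 pairs inside a run by 0.0678 at most. Different plant material may lie behind the 400 ppm sets, since 17 genes had 10 CPM or more in controls of one run and under 0.1 CPM in the other, against 0 in pairs inside a run. There were 0 such genes between the 650 ppm control runs, and 41 between SI-9 libraries 1 and 2 and library 3 at 650 ppm, all of 1 run, where library 3 lies nearer to SI-9 library 2 (0.438) and control library 4 (0.447) at 400 ppm than to its group (0.484 to 0.496), and so both a batch particular to 1 CO2 level and whether near-identical libraries come from the same plants stay open. Named genes show such on and off levels between groups too. Eucgr.C04162.1 averaged 0.0807 and 0.281 CPM in control and SI-12 roots at 400 ppm, and 209 CPM in control roots at 650 ppm. Inside the SI-9 group at 650 ppm it held 168.6 and 170.7 CPM in libraries 1 and 2 and 0.1624 CPM in library 3. For such genes plant material and treatment were not separated.

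SI-9 library 2 at 400 ppm lay between the other SI-9 libraries and SI-12 libraries. RNA or reads of SI-12 roots in this library is a candidate explanation, as the shares from genes found in only 1 source sum to 0.952, and a computed blend differed from the library by a coefficient of variation of 0.042. An exchanged label is argued against, since its nearest library of another group differs by 0.29. A plant response between the groups and a mixture cannot be told apart: the shares had a narrow interquartile range of 0.0656 over 21 genes of at least 10 CPM, but 0.321 over the 266 of 1 to 10 CPM, where counting noise around 1 share gave at most 0.203 in 100 simulations. Those simulations leave out the spread between SI-12 libraries.

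Eucgr.B01584.1 differed 4-fold among SI-12 libraries at 650 ppm that otherwise differ little. Reads shared with a near-identical gene are argued against, since in each library a share of 1 of its reads matched only this gene. A different amount of tissue that responds to the fungus is argued against by genes that rose in SI-9 roots at 650 ppm: their median log2 ratio between the libraries with most and least of it was 0 over 2425 genes, and -0.00523 (quartiles -0.195 and 0.209) over the 1872 of at least 1 CPM. RNA that is absent from control roots may rise with it, since a share of 0.507 (36 of 71) of the genes under 1 CPM in all controls and at 5 CPM or more in an SI-12 library at 650 ppm rose at least 2-fold and 0 fell, against 74 higher and 22 lower of all 17856 genes of at least 5 CPM, close to the bound of 0.5 set for that test. The origin of that RNA stays open, and whether it comes from the fungus was not tested.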

How the results depend on the processing

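Alternatives that count near-identical libraries once, use unique reads or leave out Eucgr.B01584.1 were chosen after seeing the data; the others were fixed in advance. All 12 counts of called genes and both overlaps stayed within 1.5 times under RLE and upper-quartile factors, both other filters, DESeq2, unique reads, the library block, the replicate block and without Eucgr.B01584.1. With controls of the same library run the 4 comparisons of a strain with controls and both overlaps stayed within that range too. The replicate block fit left out some libraries, and the library block assumes a run effect shared by both CO2 levels. No named gene changed sign under an alternative that gave it a value, and with a library left out 1076 values kept their call and 28 lost it. Without a filter, 47 named calls were kept and 1 was lost. Pseudocounts and gene-list alternatives were not run, since the files hold counts and the lists could not be applied. Depth limits single libraries to levels above 0.0993 to 0.667 CPM.

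Of 47 same-numbered pairs of libraries, 3 had deviations from their group means correlated above 0.1 (-0.133 to 0.152). Pairs with different numbers were not compared, so a pairing by replicate number is neither shown nor excluded. The replicate block fit held libraries 1 to 3 of each group, and control libraries 1 to 5 for CO2 in control roots. Of the 400 ppm controls it thus kept 1 near-identical set, except for CO2 in control roots. Its counts, in the order of the report, were 9127, 5982, 9153, 9100, 9991, 7060, 9919, 8438, 4633, 7358, 9460 and 8218, and the overlaps 3000 at 400 ppm and 5764 at 650 ppm.

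A 2-fold minimum, which keeps fewer genes by construction, left 5118 genes for CO2 in control roots, 3007 (SI-9) and 4670 (SI-12) against controls at 400 ppm, 4706 and 5198 at 650 ppm, 3094 and 5146 for CO2 in SI-9 and SI-12 roots, 3853 and 2275 between strains at 400 and 650 ppm, 4831 and 5612 for the interactions with CO2, and overlaps of 1406 and 2557. Fitting only the groups compared gave 3266 for CO2 in SI-9 roots; the cause was not tested.

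Counting near-identical libraries once, which leaves 10 replicates, gave 439 for CO2 in control roots, 0 for SI-9 and 0 for SI-12 at 400 ppm, 584 and 150 at 650 ppm, 0 and 0 for CO2 in SI-9 and SI-12 roots, 0 and 0 between strains, 101, 21 and 0 for the interactions of SI-9, SI-12 and strain, and overlaps of 0 and 112. Without SI-9 library 2 at 400 ppm (9 sets) these were 97, 0, 4, 161, 13, 0, 3, 2, 0, 0, 3 and 0, with overlaps of 0 and 12. DESeq2 on the 10 sets gave 3139, 1181, 1452, 3617, 2479, 2061, 1392, 806, 568, 1875, 1285 and 1134, with overlaps of 464 and 1481. Of the 48 named calls, 2 kept their side of the threshold in edgeR with 10 sets and 46 did not, while DESeq2 on these sets kept 39 and lost 7; with 9 sets 2 other calls passed and 46 did not, and none of these changed direction.

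Leaving out each library in turn gave 10471 to 12583 for CO2 in control roots, 3778 to 7256 and 6807 to 9868 for SI-9 and SI-12 at 400 ppm, 8030 to 10318 and 8640 to 11731 at 650 ppm, 4488 to 7617 and 7452 to 10362 for CO2 in SI-9 and SI-12 roots, 4484 to 8950 and 2527 to 4507 between strains at 400 and 650 ppm, 6109 to 8336, 7584 to 9995 and 5702 to 8583 for the interactions, and overlaps of 1737 to 2950 and 5181 to 6368. In most comparisons the highest count came without SI-9 library 3 at 650 ppm. This held in some comparisons that do not use that library, as with 7256 for SI-9 at 400 ppm and 10362 for CO2 in SI-12 roots. The count for SI-9 at 400 ppm was 4100 without SI-9 library 1 and 3778 without library 3, both at 400 ppm. Between strains at 650 ppm it was 2527, 2576 and 2614 without SI-12 libraries 1, 2 and 3, and at 400 ppm 5026 and 4484 without SI-9 libraries 1 and 3.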

Other observations

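Genes named in the first paragraph were chosen after their values were seen, and the tests of splits of sets and of neighbouring genes were written before their results were seen. In the 12 mycorrhizal libraries 116 genes lay above and 159 below all 11 controls. With the 10 sets as units 1105 genes parted mycorrhizal from control sets by any gap, against a median of 184 in other splits of the sets (3 of 210 as large). Eucgr.H01083.1 held 3.86 to 61.3 CPM in mycorrhizal and 0 to 0.332 CPM in control roots, and Eucgr.A02109.1 8.04 to 40.7 against 0.169 to 2.26 CPM. Whether reads of the fungus were assigned to genes that are higher in mycorrhizal libraries was not tested. Eucgr.B02924.1 lay at 12.5 to 59.3 CPM in mycorrhizal and 137 to 187 CPM in control roots, and Eucgr.G02143.1 at 0 to 1.02 against 3.14 to 17 CPM. In all, 9 genes were at least 2-fold higher and 4 at least 2-fold lower in each mycorrhizal library than in any control, and 298 genes were called higher and 378 lower in all 4 comparisons of a strain with controls. Those calls take 23 libraries as replicates. With the 10 sets as replicates edgeR called 0 genes in both comparisons at 400 ppm, and so none in all 4.

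A hypothesis is that contact with the fungus, and CO2, change some genes in spite of the differences between sets. With the 10 sets as units, 22 genes parted mycorrhizal from control sets at least 2-fold, and 3 of the 210 splits into groups of these sizes parted as many (highest other 33). Among these was the split of control roots at 650 ppm and SI-9 roots at 400 ppm against all other sets. For CO2, 26 genes parted 650 from 400 ppm sets, and 1 of 126 splits, the real one, parted as many (highest other 23). Without SI-9 library 2 at 400 ppm the numbers were 24 genes (4 of 126 splits, highest other 31) and 28 genes (2 of 126, highest other 31). Another split then parted more genes than CO2 did, and for the fungus another split parted more in both cases. Few splits of the sets parted as many genes, but those that did were not all splits by treatment. The numbers do not separate the fungus from other differences between sets, and sets that share plants or a growth batch would not be exchangeable.

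Called genes lay next to each other in ID order more often than chance. In control roots, 27.7% of the genes called for CO2 were followed by a gene called in the same direction, against 21.4% on average in permuted order, and for SI-12 against SI-9 at 650 ppm 13.9% against 7.46%. In each of the 12 comparisons 0 of 1000 permutations within an ID letter gave a share as high, also among the 17424 genes with at least 99% of reads matching 1 gene only (24.6% against 21.1% for CO2 in control roots). Neighbouring IDs may stand for neighbouring genes, which was not tested here.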
